A study of Mus musculus with 7 samples.

How the data were processed

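The deposited matrices held raw UMI counts per gene and barcode, per the file headers and values, with 27998 genes in the in-tube and fibroblast files and 31053 in the lymph node and tumour files. Per the submitters' processing notes, reads were aligned to mm10 and counted with Cell Ranger 3.0.2, while the file headers name version 3.0.0 for the lymph node and 3.0.2 for the tumour files. The labels give 10x Chromium v3 chemistry for all 7 libraries, but only the tumour files use the larger barcode list of that version, so kit and tissue differ together. The fibroblast file was already filtered (7742 barcodes), and the others held every barcode of the list. Read quality and mapping shares were not used here. The files held no features for the region barcodes, so the planned comparison of regions was not run. Antibody or raw sequence data were not used here.

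Cells needed at least 1000 UMIs, 500 genes and at most 10% mitochondrial UMIs. Scrublet scores were computed for every library, and its automatic threshold called 298 doublets (2.58%) in in-tube design 2 and 0 to 3 in each other library. The share of barcodes expected to be doublets, 0.8% per 1000 barcodes, was therefore taken from the highest scores, a rule chosen after those calls were seen. It removed 973 and 1065 barcodes of in-tube designs 1 and 2, 423 fibroblasts, 488 and 233 lymph node barcodes and 341 and 136 tumour barcodes. The mitochondrial limit removed 13 and 27 lymph node, 472 and 476 tumour, 807 and 556 in-tube and 470 fibroblast barcodes.

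Each library was clustered alone with scanpy 1.11.5 (2000 variable genes, 30 principal components, 20 neighbours, Leiden resolution 1, seed 1). Clusters were named from fixed markers of 14 cell classes, and at least 3 markers had to be detected. A first scoring rule, the mean of scaled marker values, was replaced after its names were seen by that mean times the mean share of the cluster's cells with a UMI of each marker. Clusters stayed unnamed where no class stood out, where markers of another class were more common among the 10 leading genes, or where depth was low and no marker led. The T cell markers include Tcf7, Il7r and Foxp3, which also belong to fixed lists, so these genes took part in the naming of the class in which they were tested.

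For each class with at least 50 cells in all 4 lymph node and tumour libraries, UMIs were summed per library and tested with edgeR 4.0.16 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest) in R 4.3.3, tumour against lymph node, with Benjamini-Hochberg adjustment at 0.05. B-like and monocyte/macrophage-like cells did not reach 50 cells in every library and were not tested. The biological coefficient of variation was 0.162 in T-like, 0.145 in NK-like and 0.304 in conventional DC-like cells. The p-values measure only the spread between these samples, since the labels do not say how many animals they come from. Between the libraries of a tissue the counts spread more than sampling allows, with a chi-square per degree of freedom of 26.5 in the tumour pair and 17.9 in the lymph node pair.

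Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation beside it, adjusted over the lists of a class (22 in T-like, 17 in NK-like and 19 in conventional DC-like cells). A list needed 4 tested members. With an estimated correlation no list was called in any class, and the smallest adjusted p was 0.446 in T-like, 0.334 in NK-like and 0.663 in conventional DC-like cells. With 2 libraries per tissue few degrees of freedom remain for that version. It had little power and cannot decide whether a call holds. The difference between classes was tested as an interaction in 1 edgeR model of the NK-like and T-like sums with a term for each library, a test chosen after both results were seen.

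Named genes are the 10 largest and 10 smallest log2 fold changes per class among genes with an adjusted p under 0.05, both tumour libraries on the same side of both lymph node libraries, and at least 50 CPM in both libraries of the higher group. Antigen receptor segments, unnamed gene models, pseudogenes, Xist and Y-linked genes were left out. Members of the 24 fixed lists were named as well. Genes of the in-tube libraries were ranked by the interval bound nearest 1, with at least 50 CPM in the higher library. The intervals are exact conditional binomial intervals.

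Free RNA was profiled in barcodes with under 100 UMIs. Its share of a class was scaled on genes the class should lack, C1q and Cd79 genes for T-like and NK-like cells and T cell genes for conventional DC-like cells. It came to 6.85% and 3.66% of the tumour and 6.48% and 16.6% of the lymph node UMIs in T-like cells. It was 2.59% and 3.31% against 0% and 0% in NK-like cells, and 38.3% and 27.6% against 10.0% and 12.9% in conventional DC-like cells. The tumour shares are upper limits, because UMIs of the scaling genes from doublets, mixed clusters or the cells themselves would count as free RNA. Tumour DC-like cells had medians of 16231 and 23138 UMIs, so their shares far exceed the 100 UMIs under which free RNA was profiled. Tumour T-like cells had medians of 9246.5 and 9556.5 UMIs, so their shares exceed it as well. The 0% of lymph node NK-like cells does not cover T cell RNA.

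The tests were checked on simulated data with 200 changed genes. At true log2 changes of 1, 2 and 3 they recovered 62.1%, 85.1% and 100% in T-like cells, 22.7%, 67.2% and 82.1% in NK-like cells and 1.52%, 44.8% and 82.1% in conventional DC-like cells. Of 179, 116 and 91 calls in all, 14, 1 and 5 were unchanged genes. The rates rest on a single simulated draw per class. Far more genes were called in the real T-like (5992) and NK-like (786) data than the 200 changed here, so the rates need not hold there. The interaction test recovered 40.0% and 63.0% at log2 2 and 3 and called 4 unchanged genes. The counting intervals of ratios covered 95.4% to 95.8% of simulated true values.

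The comparisons, lists, markers, thresholds, tests and most alternatives were fixed before the data were examined. Chosen afterwards were the doublet and scoring rules, the naming of every cluster by its best class, leaving out shared barcodes, subtracting free RNA, leaving libraries out of the shares, and comparing the neutrophil-like clusters of the in-tube libraries singly. So were the interaction test with its alternatives, the tests of library kit, and the tests of shared barcodes and melanocyte genes except those of mCherry and of unrelated pairs. The rule that the mCherry test is void was added after 0 mCherry UMIs were seen in both whole tumour libraries. A further 3 predictions, on macrophage genes in tumour T-like cells, were removed untested. Regions within a library were not compared. A member of the naive and recirculating list is not reported here.

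Software also included DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. The alternatives were DESeq2's Wald test, median-ratio size factors, no low-count filter, looser cells (500 UMIs and 300 genes) and stricter cells (2000 UMIs and 1000 genes). They also covered a mitochondrial limit of 20%, doublets kept, Leiden resolution 0.5, counts thinned to the smallest library, the 100 genes most abundant in free RNA left out, and each library left out in turn.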

Results

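ZipSeq marks living cells of chosen regions with light-released DNA barcodes and then reads their RNA cell by cell. The series held 7 mouse libraries of droplet single-cell RNA. A pair of libraries came from CD45+ immune cells of live lymph node sections, where cells of 2 regions (lymph node library 1) or 4 regions (lymph node library 2) were to be told apart. Another pair (tumour libraries 1 and 2) came from CD45+ immune cells of PyMT ChOVA tumours, mammary tumours driven by the polyoma middle T antigen that carry mCherry and ovalbumin. The in-tube tests of barcode designs 1 and 2 used primary mouse immune cells, with 1 library each. The last library held NIH3T3 cells, a mouse fibroblast line, from a wound healing assay. The files held no feature for the region barcodes, so cells are compared here between libraries and not between regions.

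The libraries differed in depth. They held 22534883 and 23078130 UMIs (unique molecular identifiers, 1 per counted molecule) in the lymph node pair and 155549128 and 110202755 in the tumour pair. The in-tube libraries held 129315913 for design 1 and 100824823 for design 2, and the fibroblast library 94050934. After filtering, 7325 and 5167 lymph node cells remained with medians of 2201 and 3350 UMIs per cell, and 6183 and 3992 tumour cells with medians of 15336 and 13836.5. The in-tube libraries kept 10055 and 10473 cells with medians of 7770 and 5244 UMIs. The fibroblast library kept 6848 cells with a median of 11365.5 UMIs.

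The tumours were rich in monocyte/macrophage-like cells and the lymph nodes in T-like cells. T-like cells, named from Cd3e, Trac, Lck and other T cell markers, made up 79.8% (78.8% to 80.7%) of lymph node library 1 and 79.2% (78.1% to 80.3%) of library 2. They made up 14.3% (13.4% to 15.2%) of tumour library 1 and 36.3% (34.8% to 37.8%) of tumour library 2. Monocyte/macrophage-like cells made up 55.3% (54.0% to 56.5%) and 39.0% (37.5% to 40.6%) of the tumour libraries. No lymph node cluster took that name, but the smallest clusters there held 46 and 39 cells, so fewer such cells would lie within clusters of other names. B-like cells were 11.6% and 5.57% of the lymph node cells and 2.30% of tumour library 2, and no cluster of tumour library 1 was B-like. NK-like cells, the cytotoxic lymphocytes of innate immunity, were 0.819% and 1.34% of lymph node cells against 3.01% and 7.31% of tumour cells. Conventional dendritic cell (DC)-like cells were 1.47% and 2.17% against 1.70% and 4.33%. Neutrophil-like cells (4.22%) were named in tumour library 1 alone, as were fibroblast-like cells (0.275%), while a cluster of tumour library 2 led by Col1a1, Col1a2 and Sparc (2.53%) stayed unnamed for too few detected markers. Mast cell or basophil-like cells were 0.744% and 2.78% of the tumour libraries, and plasma-like cells 0.518% and 1.15%.

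The 2 in-tube libraries were made up of different cells. Design 1 was 80.8% (80.0% to 81.6%) T-like and 4.20% (3.81% to 4.61%) monocyte/macrophage-like. Design 2 was 24.2% (23.4% to 25.1%) T-like and 24.1% (23.3% to 25%) monocyte/macrophage-like, with 8.65% neutrophil-like, 8% conventional DC-like and 6.52% B-like cells. Intervals are exact binomial 95% intervals and cover counting error only. With 2 libraries against 2, the smallest exact permutation p is 1 in 3, so the shares were not tested. Clusters left unnamed held 5.22% and 9.58% of the lymph node cells, 20% and 5.96% of the tumour cells, and 11.0% and 28.2% of the in-tube cells. All unnamed lymph node cells scored highest as T-like, and most of them lay in clusters led by Ccl5, Ly6c2 and Klra7, genes of memory-like CD8 T cells (4.59% and 9.58% of all cells).

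**Figure D1:**
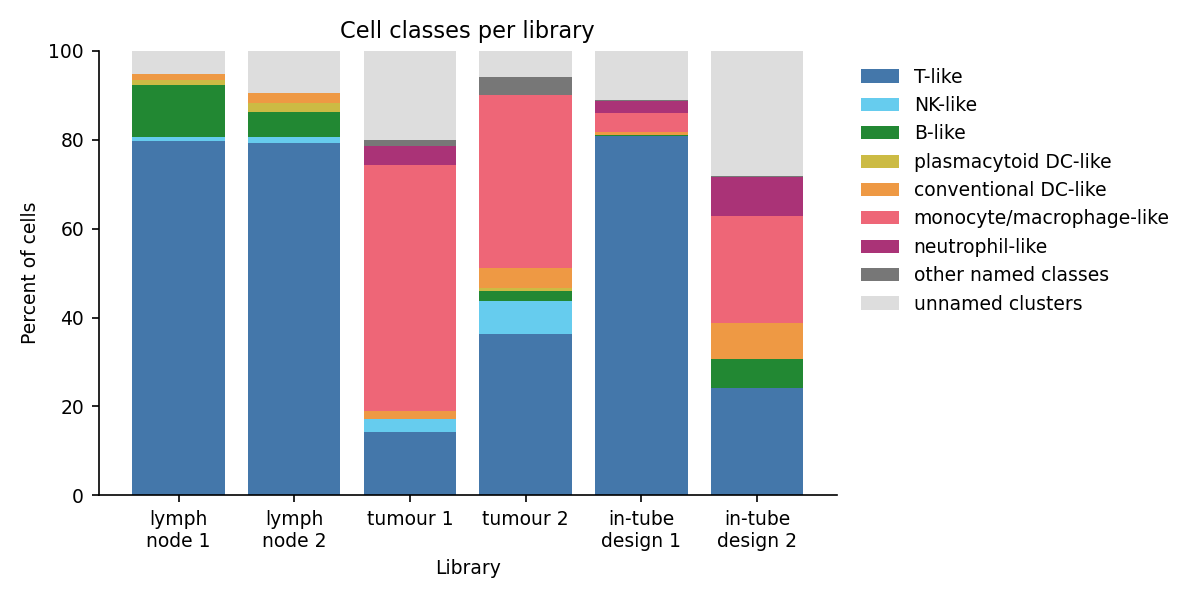
Percent of cells in each class (vertical axis) for the lymph node, tumour and in-tube libraries (horizontal axis), 1 stacked bar per library. T-like cells were 79.8% and 79.2% of the lymph node libraries, and monocyte/macrophage-like cells 55.3% and 39.0% of the tumour libraries.

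Summed over cells, T-like cells of the tumours carried more RNA of killing, checkpoint and G2/M genes than T-like cells of the lymph nodes, and less of the naive programme. Every one of 10 cytotoxic effector genes and of 10 exhaustion and checkpoint genes rose, and 9 of 10 naive and recirculating T cell genes fell. Gzmk, a granzyme of effector memory CD8 T cells, stood at 126 ± 87.2 CPM (counts scaled to library size) in the tumours and 0.297 ± 0.324 CPM in the lymph nodes (SD, n = 2 each). Gzmb, the granzyme of armed killer cells, stood at 578 ± 213 against 5.34 ± 3.14 CPM. Ccr7, the chemokine receptor that brings T cells into lymph nodes, fell from 1379 ± 163 to 69.7 ± 2.38 CPM. Klf2, a transcription factor of resting, recirculating T cells, fell from 2632 ± 157 to 192 ± 86.8 CPM. The 4 libraries held 5844 and 4093 lymph node and 882 and 1450 tumour T-like cells, with medians of 2200, 3273, 9246.5 and 9556.5 UMIs. In edgeR's quasi-likelihood test, 5992 of 11999 genes changed after Benjamini-Hochberg adjustment, 3211 higher and 2781 lower in the tumours. Without lymph node library 1 the count was 3431, of which 3380 were among the 5992, all in the same direction.

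Among genes of at least 50 CPM in both tumour libraries, the 10 with the largest rise mixed genes of T cells with genes of macrophages. Gzmk rose by a log2 fold change of 8.28 (standard error 0.82, adjusted p = 0.000441), and Gzmb by 6.32 (0.50, adjusted p = 0.000209). Ccl3, a chemokine of activated killer cells, rose by 6.37 (0.26, adjusted p = 3.64e-05) and Hip1, an endocytic adaptor, by 6.98. Each gene named here was higher, or lower, in 2 of 2 tumour libraries than in both lymph node libraries, as the naming rule required. Spp1 (osteopontin, abundant in tumour macrophages) rose by 7.34, Ccl8 by 9.24, the complement genes C1qb, C1qa and C1qc by 7.22, 6.68 and 6.48, and Wfdc17 by 6.30. Free RNA, profiled in barcodes with under 100 UMIs, was estimated as an upper limit. It could account for up to 100% of the tumour T-like counts of Ccl8 and 98.2% of those of Wfdc17. At the depth of these cells this limit exceeds 100 UMIs per cell. Doublets, mixed clusters or the cells themselves are therefore not excluded as sources. The estimate took the C1q and Cd79 genes of T-like and NK-like cells to be free RNA, so it says nothing about the source of the C1q genes. It accounted for at most 10.9% of Spp1, 11.6% of Ccl3, 6.86% of Hip1, 1.48% of Gzmb and 1.06% of Gzmk. The values that a single library moved by over 1.5 times ranged from 8.72 (without lymph node library 2) to 10.13 (without lymph node library 1) for Ccl8. They ranged from 7.18 (without tumour library 2) to 10.37 (without lymph node library 2) for Gzmk and from 6.19 (without tumour library 1) to 8.13 (without lymph node library 2) for Spp1. For Hip1 they ranged from 6.20 to 8.55 (without lymph node library 1 and 2), and Gzmb reached 7.17 without lymph node library 2.

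Among the genes with the largest falls, Ly6c1, a surface protein of resting T cells, fell by 6.44 on the log2 scale (0.22, adjusted p = 2.66e-05), from 81.1 ± 6.73 to 1.28 ± 0.302 CPM. Igfbp4, which binds insulin-like growth factors, fell by 5.32, Ccr7 by 4.74 and Klf2 by 4.19. Ifngr2, a chain of the interferon gamma receptor, fell by 4.07, and Dusp10, a phosphatase that restrains MAP kinases, fell by 3.74. Pik3ip1, an inhibitor of PI3 kinase, fell by 3.70, Rnaset2a, a ribonuclease, fell by 3.67, and Tsc22d3 (GILZ), a glucocorticoid-induced gene, fell by 3.53. Rps27rt, a copy of a ribosomal protein gene, fell by 4.16. Without tumour library 2, Klf2 changed by −4.85 and Pik3ip1 by −4.40.

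Among the fixed gene lists, the cytotoxic effector genes rose together (10 of 10, median log2 4.68). Ifng, the signature cytokine of killer and helper type 1 cells, rose by 4.63, Ccl4 by 4.72, Gzma by 4.91, Ccl5 by 3.92, the pore-forming Prf1 by 1.79 and Nkg7, a granule protein, by 1.17. The NK receptor genes Klrc1 (5.47), Ncr1 (4.09) and Klrb1c (3.46) moved with them in the T-like class. A Klra7-led cluster held 366 of the 1450 T-like cells of tumour library 2. Tyrobp rose as well (2.34), while the T cell marker Cd3e changed by −0.95. Whether NK cells lay within the tumour T-like clusters was not tested. The exhaustion and checkpoint genes rose too (10 of 10, median 2.43), with the inhibitory receptors Havcr2 at 6.40, Lag3 at 3.72, Pdcd1 at 3.66, Tigit at 2.67 and Ctla4 at 1.34. The ectoenzyme Entpd1 rose by 4.86 and the costimulatory receptor Tnfrsf9 by 2.19. All 7 regulatory T cell genes rose, among them Il10 (2.34), the lineage factor Foxp3 (1.5) and Ikzf2 (1.42). All 12 G2/M genes rose, among them Mki67 (3.56), Cenpf (2.32) and Top2a (2.14). UMIs were summed, so deep cells weigh more in these values. The dividing clusters held 110 of 882 and 101 of 1450 T-like cells of tumour libraries 1 and 2. Their medians were 35847.5 and 27139 UMIs, against 9246.5 and 9556.5 in all T-like cells. Of 13 S phase genes, 5 rose, Ung fell by 1.21 and 7 were not called. All 9 hypoxia genes rose, with Bnip3 at 2.11 and the glucose transporter Slc2a1 at 1.13. Of 11 glycolysis genes 7 rose, with Tpi1 at 2.07, Pfkp at 1.76 and Gapdh at 1.47, while Ldha (0.18) was not called. Of the 10 naive and recirculating genes, the transcription factors Lef1, Satb1 and Tcf7 changed by −3.39, −1.69 and −1.67. Dapl1 changed by −3.08 and the egress receptor S1pr1 by −2.68. Of 10 ribosomal protein genes 8 fell, 9 when adjusted over the list alone, with Rps27 at −2.36, Rpl41 at −1.81 and Rps18 at −1.54.

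Limma's camera with a preset correlation called these lists (adjusted p = 7.33e-16 cytotoxic, 2.13e-14 exhaustion, 0.00272 regulatory T, 5.62e-08 G2/M, 0.00272 hypoxia, 0.00492 glycolysis, 7.33e-16 naive and 9.67e-06 ribosomal) but not the S phase list (0.61). No list was called in T-like cells with an estimated correlation. There adjusted p = 0.446 for the cytotoxic, exhaustion, G2/M, hypoxia, naive and ribosomal lists and 0.452 for the regulatory T and glycolysis lists. The same 0.446 stood for lists with preset values from 7.33e-16 to 0.00272. With 2 libraries per tissue that version had little power, so it cannot decide whether the calls hold. Counts adjusted over the list alone were the same as over all genes for every other list of the previous paragraph. Single libraries moved Havcr2 (5.36 without lymph node library 1 and 12.08 without library 2), Gzma (3.87 without tumour library 2 and 5.49 without tumour library 1) and Ccl5 (2.92 without tumour library 2 and 5.34 without lymph node library 2). Different clusters held the class in each tissue. In the lymph nodes most T-like cells lay in clusters led by Cd8b1, Lcn4 and Itgae or by Ly6c1, Igfbp4 and Cd4. In the tumours they lay in clusters led by Cd4 and Ifng, by Cd8b1 and Gzmk, by Foxp3 and Ctla4, by cell cycle genes, and by Klra7, Satb1 and Tcf7. The naming rule, set after the clusters were seen, kept the memory-like lymph node clusters out of the class. With them in, the log2 change was 1.96 for Ccl5, 3.46 for Ccl4, 7.70 for Gzmk and 6.24 for Gzmb, each still called.

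**Figure D2:**
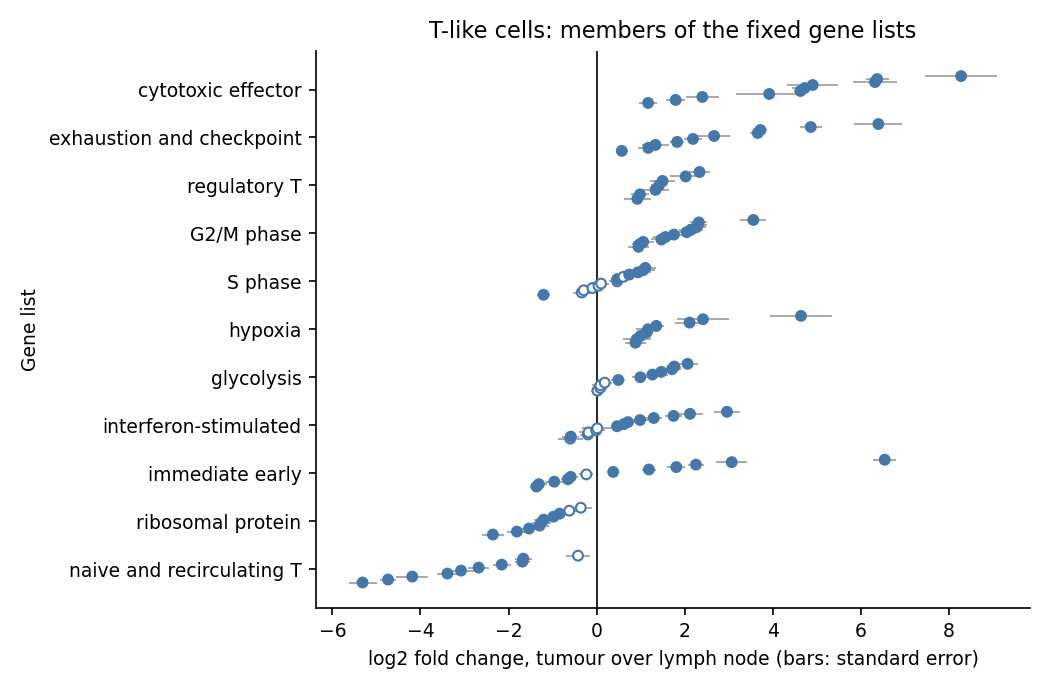
Log2 fold change of tumour over lymph node in T-like cells (horizontal axis) for the members of 11 fixed gene lists (vertical axis), 1 point per gene with its standard error; filled points passed the test. All 10 cytotoxic and all 10 exhaustion and checkpoint genes lie to the right of 0, and 9 of 10 naive genes passed the test to the left.

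Stress and interferon genes of T-like cells moved both ways. Of 14 interferon-stimulated genes 8 rose, among them Isg15 (1.75), Ifit3 (0.99) and Ifit1 (0.71), and Irf7, a regulator of the response, fell by 0.59 (camera adjusted p = 0.0509). Of 12 immediate early genes, 6 rose, with Ier3 at 6.54, Egr1 at 2.26, Fosb at 1.81 and Zfp36 at 1.19, and 5 fell, with Jun at −1.37 and Junb at −1.31 (camera adjusted p = 0.112). Of 8 heat shock genes 4 rose, the inducible chaperones Hspa1b (8.05) and Hspa1a (7.24) most, and 1 fell (0.0976). Without tumour library 2 the values were 6.84 and 6.06, and without tumour library 1 8.68 and 7.86. Tyms, of the S phase list, rose by 1.06. The calls were lost without lymph node library 2 for Ifit1 (0.47), without lymph node library 1 (−0.34) or tumour library 2 for Irf7, and without lymph node library 1 for Tyms (0.75). Mitochondrially encoded genes split as 4 up and 3 down of 10 (0.828). Counts adjusted over the list alone were the same for these lists.

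Lists that mark other cell types also rose in tumour T-like cells. All 7 complement macrophage genes rose (camera adjusted p = 2.37e-14), as did 11 of 12 lipid-associated macrophage genes (2.10e-08), 6 of 7 MHC class II genes (0.00272), all 4 measured matrix genes (0.00299) and 4 of 5 genes of cross-presenting DCs (0.00847). With an estimated correlation, adjusted p = 0.446 for the complement, lipid-associated and matrix lists and 0.452 for the others. Counts adjusted over the list alone were the same, except that 1 MHC class II gene also fell. Free RNA could account for up to 100% of the counts of Apoe (log2 3.54), the lipid carrier of macrophages, 70.9% of Cd74 (1.55), the MHC class II chaperone, and 57.5% of Ier3. After this upper limit of free RNA was subtracted, the fitted change was −9.73 for Apoe, 14.68 for Cd74 and 6.75 for Ier3. Subtraction thus reversed the rise of Apoe but not those of Cd74 and Ier3. By the same estimate, free RNA made up 6.48% and 16.6% of lymph node T-like UMIs. Other lists were not called, with adjusted p = 0.235 for classical monocyte (3 rose and 1 fell of 6), 0.61 for germinal centre B (3 rose and 2 fell of 5), 0.55 for matrix remodelling (2 rose of 4) and 0.0976 for mature DC genes (1 rose and 1 fell of 6). Of 3 contractile genes 2 rose and 1 fell, and of 3 targets of the growth regulator YAP 2 rose, too few for a list test.

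NK-like cells of the tumours carried less RNA of immediate early and resting lymphocyte genes than those of the lymph nodes, and more mitochondrially encoded RNA. Il7r and others of the resting genes are also T cell genes, and T cell RNA in the lymph node sums was not estimated. Nr4a1, an immediate target of receptor signalling, fell from 430.3 ± 126 to 79.7 ± 20.7 CPM (SD, n = 2 each; log2 −2.54, standard error 0.25, adjusted p = 1.41e-07). Il7r, the receptor for the survival cytokine interleukin 7, fell by 2.61 on the log2 scale. Ccl1, a chemokine of activated lymphocytes, stood at 563 and 94.6 CPM in the tumour libraries and at 1 UMI in both lymph node libraries together, a ratio of 109 (95% counting interval 19.5 to 4295). The class held 60 and 69 lymph node cells and 186 and 292 tumour cells, with 172895 to 2536360 UMIs per library. In edgeR's quasi-likelihood test 786 of 7505 genes changed, 386 higher and 400 lower. The count was 548 to 762 with a library left out, of which 433 to 558 were among the 786, in the same direction.

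Among genes of at least 50 CPM in both tumour libraries, those that rose most in NK-like cells had few or no lymph node counts. Their folds are therefore bounds or wide ratios. Against a floor of 3 counts over both lymph node libraries, Spp1 was at least 24.3-fold higher, Ccl8 at least 13.8-fold, C1qb at least 12.7-fold and C1qa at least 10.6-fold. Free RNA, scaled on the C1q and Cd79 genes, could account for up to 68.3% of the counts of Ccl8 and at most 6.53% of those of Spp1. With 1 or 2 lymph node UMIs each, the ratios were 50.5 (9.03 to 1999) for Lars2, a mitochondrial leucyl-tRNA synthetase, and 25.2 (4.49 to 999.7) for Egln1, an oxygen-sensing hydroxylase. They were 24.0 (4.27 to 951) for the splicing helicase Snrnp200, 19.8 (3.51 to 784) for the antiviral gene Ifitm3 (up to 88.3% free RNA) and 18.5 (5.08 to 153) for Ly6a. Each of these genes was higher in 2 of 2 tumour libraries, as the naming rule required, with adjusted p = 7.36e-07 for Spp1 and 4.80e-06 for Lars2. Leaving out a library moved every fitted value of these 10 genes by over 1.5 times, from 5.12 (without tumour library 1) to 11.93 (without lymph node library 2) for Ccl1 and from 4.52 to 10.68 (without lymph node library 2 and 1) for Lars2. The range was 3.66 to 9.64 for Egln1 and 3.18 to 10.15 for Ly6a (without lymph node library 1 and 2), and 3.40 to 9.57 for Snrnp200 and 3.12 to 9.29 for Ifitm3 (without lymph node library 2 and 1). It was 10.18 (without tumour library 1) to 11.24 (without lymph node library 1) for Spp1. Without tumour library 2 and lymph node library 1 it was 8.81 to 10.30 for Ccl8, 8.70 to 10.18 for C1qb and 8.75 to 9.96 for C1qa.

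Among the genes that fell in NK-like cells, the ribonuclease Rnaset2b fell by 3.37 (0.30, adjusted p = 2.85e-08) and its neighbour copy Rnaset2a by 3.34. Both were lower in 2 of 2 tumour libraries, as the naming rule required. Rnaset2b fell in T-like cells too (−3.27), and library kit and tissue differ together in this comparison. Pik3ip1 fell by 3.18, Rps27rt by 3.07, Nmrk1, an enzyme of NAD synthesis, by 2.83, the cell cycle regulator Rgcc by 2.70, Ccr7 by 2.45 and the T cell receptor subunit Cd3e by 2.43. Left-out libraries moved Rnaset2a (−4.39 without tumour library 2 and −2.69 without tumour library 1), Pik3ip1 (−3.95 without tumour library 2 and −2.58 without lymph node library 1) and Ccr7 (−3.44 without tumour library 1 and −1.64 without tumour library 2). The call of Nmrk1 was lost without tumour library 1 (adjusted p = 0.0564).

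By list, 8 of 12 immediate early genes fell in NK-like cells, 9 when adjusted over the list alone. The signal-induced transcription factors Junb and Ier2 changed by −1.81 and −1.69, Dusp1 by −1.56, Zfp36 by −1.10 and Fosb by −0.94. Of 9 naive and recirculating genes 5 fell (7 over the list alone), with Klf2 at −1.87, and Satb1 rose by 1.07. The T cell marker Cd3e fell beside them (−2.43), from 110 and 63.1 CPM in the lymph node NK-like sums. In lymph node free RNA, Cd3e, Cd3d, Cd3g, Lck and Lat together stood at 3875 and 3121 CPM. Free RNA of NK-like cells was scaled on other genes, so T cell RNA was not separated from the fall of this list. Of 10 mitochondrially encoded genes 6 rose (7 over the list alone), with the respiratory chain subunits mt-Nd3 at 1.85, mt-Nd2 at 1.67, mt-Nd5 at 1.63 and mt-Co2 at 1.58. Of 13 interferon-stimulated genes 4 fell (5 over the list alone) and 1 rose. The lymph node libraries stood apart from each other in this list, with Ifit1 at 0 and 175 CPM and Ifit3 at 5.78 and 107 CPM. Of 11 glycolysis genes 2 rose, with Gapdh at 1.33. Camera called these lists with adjusted p = 1.36e-12, 2.28e-07, 2.28e-07, 0.00215 and 0.0464. It also called 4 of 4 complement genes (2.11e-06) and the lipid-associated macrophage list, where 5 rose and 1 fell of 10, or 6 and 2 over the list alone (0.00282). No list was called with an estimated correlation, where adjusted p = 0.334 for the immediate early list and 0.578 for the others. That version had little power here too.

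The killer programme of NK-like cells did not pass the list test (camera adjusted p = 0.057). Of 9 cytotoxic genes, Ccl5 fell by 1.61, Nkg7 by 0.78 and Ccl3 by 0.59, and over the list alone 3 fell and 2 rose. The costimulatory receptor Tnfrsf9 rose by 2.10 and the receptor Cd160 fell by 1.08 among 7 exhaustion and checkpoint genes (0.373). Of 12 S phase genes 3 fell (4 over the list alone), with Tyms at −1.65 (0.0807), and of 6 G2/M genes Birc5, a mitotic survival gene, fell by 2.50 (0.0962). The other lists were not called either, with adjusted p = 0.116 for ribosomal protein, 0.0879 for MHC class II, 0.313 for regulatory T, 0.544 for hypoxia, 0.95 for heat shock and 0.971 for classical monocyte genes. Calls were lost without tumour library 2 (−0.18) or lymph node library 2 (−0.45) for Ccl3, and without lymph node library 1 (−0.82) or tumour library 2 (−0.60) for Fosb. They were lost without lymph node library 1 (−0.46) for Cd160 and without lymph node library 2 (−1.25) for Tyms. Without lymph node library 2 the fitted changes of Ifit1 and Ifit3 were 7.32 and 1.46.

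T-like and NK-like cells differed in the change of several killer genes. The difference was tested in a model with both classes and a term for each library. It passed for 608 of 7489 genes tested in both, and 57 of them had been called in opposite directions. Far more genes, 571, were called in the same direction in both classes. Of these 295 were higher and 276 lower, against 101 and 107 if the classes had changed independently. Ccl3, Ccl5 and Nkg7 rose in T-like and fell in NK-like cells, with differences (NK-like minus T-like) of −7.00, −5.68 and −1.94 (adjusted p = 1.95e-20, 6.29e-13 and 1.33e-07; each direction was seen in 2 of 2 tumour libraries of its class). The immediate early genes Fosb and Zfp36 and the cell cycle genes Birc5 and Tyms did the same, with differences of −2.76, −2.28, −3.91 and −2.64. Satb1, a chromatin organiser, went the other way, down in T-like and up in NK-like cells (2.76). The NK-like falls are weaker than the differences. That of Ccl3 was −0.59 (edgeR adjusted p = 0.0426), and the NK-like calls of Ccl3, Fosb and Tyms were each lost with a library left out. Among genes outside the lists, picked after their values were seen, were the NK receptor genes Klrc1 (5.47 in T-like and −1.36 in NK-like cells), Klra7 (4.79 and −0.76), Klrb1c (3.46 and −0.61) and Ncr1 (4.09 and −0.66). The naming rule bears on these values, because Klra7-led clusters were named T-like in the tumours and left unnamed in the lymph nodes. NK cells within the tumour T-like class would bear on them too, and were not tested for. With every cluster in its best class, 52 of the 57 genes still passed in opposite directions. The T-like change was then 0.98 for Klra7 (adjusted p = 0.0449), 3.29 for Klrc1, 2.05 for Klrb1c and 3.25 for Ncr1, and the differences were −6.40 for Ccl3, −3.47 for Ccl5 and −1.69 for Nkg7.

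**Figure D3:**
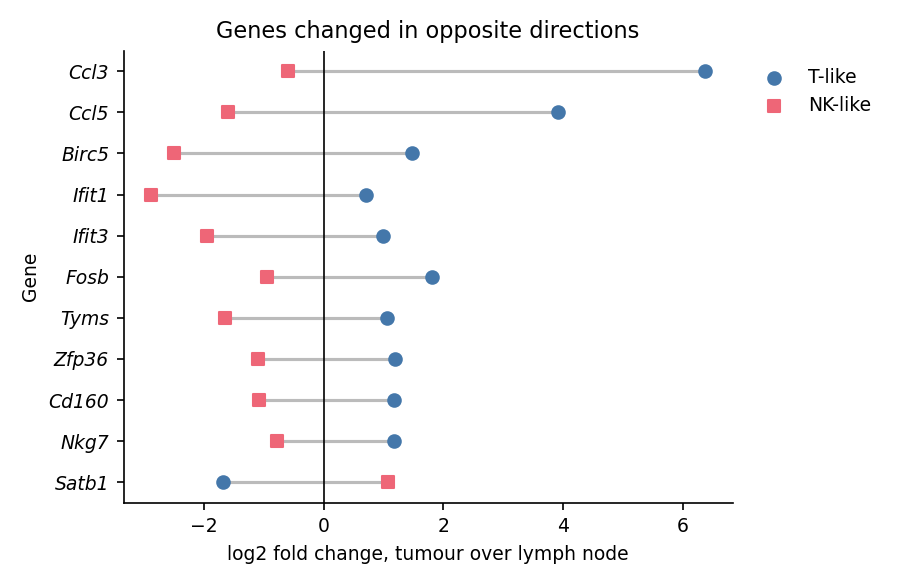
Log2 fold change of tumour over lymph node (horizontal axis) for the 11 listed genes (vertical axis) that changed in opposite directions in T-like cells (circles) and NK-like cells (squares). Ccl3 lies farthest apart, at 6.37 and −0.59, but its NK-like call was lost with a library left out.

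Conventional DC-like cells were compared between the tumours and the lymph nodes in the same way, and the number of genes called depended on the settings. Pdcd1lg2 (PD-L2, a ligand of the inhibitory receptor PD-1) stood at 145 ± 84.3 CPM in the tumours and 3.24 ± 0.755 in the lymph nodes (SD, n = 2 each; log2 5.23, adjusted p = 0.0474). Ifitm1, an antiviral membrane protein, stood at 512 ± 326.5 against 7.73 ± 3.29 CPM (log2 5.75, adjusted p = 0.0302). Lyz2, the lysozyme of myeloid cells, fell from 3047 ± 825.5 to 356 ± 163 CPM (log2 −3.34, adjusted p = 0.0302). In edgeR's quasi-likelihood test 51 of 8051 genes changed, 24 higher and 27 lower, and 1676 genes had an unadjusted p under 0.05. On simulated data the test recovered 1.52% of changes of log2 1 in this class, so the low count does not bound how many genes differ. Each gene named here was higher, or lower, in 2 of 2 tumour libraries, as the naming rule required. The class held 108 and 112 lymph node cells and 105 and 173 tumour cells, in different clusters. Both lymph nodes held a cluster led by Lyz2 and Cst3 and another led by Fscn1 and Ccl22, genes of mature migratory DCs. Tumour library 2 held a mature cluster and another led by Cd209a and Xcr1. In tumour library 1 the class held a mature cluster alone (Fscn1, Ccr7; 105 cells), because a cluster of 175 cells (2.83%) led by Ifitm1, Cd209a, Siglech and Xcr1, which scored highest as conventional DC, stayed unnamed.

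Also higher in tumour DC-like cells were AA467197 (log2 4.84), the calcitonin receptor partner Ramp3 (4.28), the cytokine signal transducer Stat4 (4.04), Lars2 (3.45), Tmem131 (3.28), Ccl8 (3.24), the cyclin Ccnd2 (3.22) and Cmip (2.93). Lower were Lyz1 (−5.48), the chaperone Clu (−4.29), Rps27rt (−3.60), Wdr91 (−2.39), Ramp1 (−2.35), Rps28 (−2.29), the lysosomal transporter Slc46a3 (−2.21), Mthfs (−2.05) and Lef1 (−3.80). Free RNA could account for up to 100% of the tumour counts of Lyz1, Lyz2, Ccl8 and Lars2, and for up to 38.3% and 27.6% of all tumour UMIs of the class. The estimate took all T cell gene UMIs of the class to be free RNA, so doublets or mixed clusters would raise it. Each of the 20 called genes lost its call without at least 1 lymph node library, with 6 genes left in all without lymph node library 1 and 0 without library 2 (778 at an unadjusted p under 0.05). Without tumour library 1 or 2 the test called 1641 and 2386 genes. The values moved to 4.97 (without tumour library 2) and 6.39 (without lymph node library 2) for Ifitm1, and to 4.20 and 6.06 (without lymph node library 1 and 2) for AA467197. Without tumour library 1 they were 4.39 for Pdcd1lg2, 3.46 for Ramp3 and 3.25 for Stat4, and Ccl8 reached 3.95 without lymph node library 1.

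By list, no immediate early gene of DC-like cells passed over all genes, but 10 of 12 did, all lower, when adjusted over the list alone. Dusp1 stood at −1.90 (adjusted p = 0.0525), Fos at −1.55, Ier2 at −1.54 and Junb at −1.14. Camera called this list (adjusted p = 1.10e-06), the naive list (6.45e-05, Lef1 fell; 5 fell and 1 rose of 10 over the list alone) and the ribosomal list (7.01e-05; 7 of 10 lower over the list alone) as lower. The T cell genes Cd3e, Cd3d, Cd3g, Lck and Lat together stood at 234 and 270 CPM in tumour against 389 and 401 CPM in lymph node DC-like sums. T cell RNA was thus not separated from the fall of the naive list. Camera called glycolysis (0.0118; 4 of 11 higher over the list alone, with Gapdh at 1.55) and G2/M genes (0.0362; 0 of 9) as higher. With an estimated correlation, adjusted p = 0.663 for each of these 5 lists.

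The in-tube libraries tested barcode designs 1 and 2 on immune cells, and design 2 cells carried more RNA of interferon-stimulated and MHC class II genes. Interferon-stimulated genes summed over the list were higher in design 2 in every class compared: 1.24-fold (1.22 to 1.25) in T-like, 2.29-fold (2.25 to 2.34) in monocyte/macrophage-like, 4.12-fold (3.71 to 4.58) in conventional DC-like and 17.3-fold (15.9 to 18.8) in neutrophil-like cells, where it was 1.95-fold with stricter cells. Of 14 members, all were higher in design 2 in T-like and neutrophil-like cells, and 13 in the other classes. MHC class II genes were 5.03-fold (4.89 to 5.18), 4.40-fold (4.29 to 4.50), 1.37-fold (1.33 to 1.40) and 9.37-fold (7.62 to 11.6) higher in the same order, although genes of myeloid cells such as Lyz2 (9.14-fold) and Fcer1g (7.91-fold) were higher in the T-like cells too and free RNA was not estimated here. The MHC class II value was 2.31-fold in conventional DC-like cells when doublets were kept and 5.13-fold in neutrophil-like cells with looser cells. Saa3, an acute phase protein, stood at 25365 CPM in monocyte/macrophage-like cells of design 2 and 30.6 CPM in design 1, an 829-fold difference (677 to 1027). Each design had 1 library, so nothing was tested between designs, and intervals cover counting error only. The classes held 8125 and 2537 T-like, 422 and 2529 monocyte/macrophage-like, 63 and 838 conventional DC-like, and 280 and 906 neutrophil-like cells of designs 1 and 2.

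In monocyte/macrophage-like cells, design 2 was also higher in the chemokines Ccl5 (85.9-fold, 79.3 to 93.2) and Cxcl3 (64.5-fold, 40.8 to 109), in Ly6i (129-fold), the scavenger receptor Marco (114-fold, 31.6 to 945), the itaconate enzyme Irg1 (71.7-fold), H2-M2 (63.4-fold) and Cd38 (60.5-fold). U90926 and Gp6 had no UMI in design 1 and stood at 122 and 119 CPM in design 2. Design 1 was higher in the neutrophil granule genes Ngp (8.47-fold), Camp (7.39-fold), S100a8 (6.91-fold) and S100a9 (5.83-fold), in Rgcc (5.19-fold) and in mt-Nd3 (8.29-fold). In design 1 this class lay in clusters led by Spp1 and Lpl or by Psap and Wfdc17, and in design 2 in clusters led by Rsad2 and Saa3, by Spp1 and Lpl, by Ppbp and Egr1 and by Asgr2. In neutrophil-like cells, design 2 was higher in Ccl5 (1575-fold, 921 to 2957), Saa3 (858-fold), Ly6i (235-fold), Clec4n (221-fold), the antiviral genes Rsad2 (213-fold) and Ifit1 (177-fold), and the monocyte attractant Ccl2 (143-fold). Design 1 was higher in genes of granules and of young neutrophils, with Stfa1 at 16.8-fold, Camp at 7.04-fold, Ltf at 5.80-fold and Mki67 at 9.53-fold. All 12 G2/M genes (median log2 1.70) and all 12 measured S phase genes (1.29) were higher in design 1 in these cells. Different clusters held the class: design 1 had a single cluster led by S100a8, Ngp and Camp, and design 2 had a like cluster of 317 cells and another of 589 cells led by Lcn2, Slpi and Ly6i. Against design 1, the like cluster alone was 3.57-fold (3.25 to 3.93) higher in interferon-stimulated genes, 8.31-fold in MHC class II genes, 83.2-fold in Ccl5 and 23.6-fold in Saa3, with ratios of 0.567 for Camp, 0.755 for Ltf, 0.162 for Stfa1 and 0.355 for Mki67. Conventional DC-like cells of design 1 lay in a cluster led by Cd74 and H2-Aa, and those of design 2 in clusters led by Ccl22 and Ccl17 and by Fscn1. In these cells, Isg15 was 43.7-fold (20.1 to 119) and Il6 80.1-fold (14.4 to 3167, 1 UMI in design 1) higher in design 2, and Saa3, Irf7, Ifit1, Ptgs2, Acp5 and Pltp had no UMI in design 1.

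In T-like cells, design 2 was higher in Saa3 (6850-fold, 3324 to 17041), H2-Aa (30.1-fold), Cd74 (24.9-fold), Ccl5 (11.2-fold, 10.9 to 11.5), Pf4 (10.7-fold), Lyz2 (9.14-fold), Apoe (8.16-fold), Fcer1g (7.91-fold), Ifitm3 (6.05-fold) and H2-T23 (5.88-fold). Most of these are genes of myeloid cells, and Saa3 stood at 582 CPM in T-like cells against 25365 CPM in monocyte/macrophage-like cells of the same library. The class lay in different clusters, in design 1 led by Ly6c1 and Cd4, by Mt2 and Gzmb, by Igfbp4 and by Cd8a, and in design 2 mostly by Cd8b1 and Cd8a (859 and 817 of 2537 cells). Design 1 was higher in the replication-dependent histone genes Hist1h2an (8.91-fold, 7.61 to 10.5), Hist1h4d (6.92-fold) and Hist2h2ac (4.98-fold), in Gzma (4.01-fold), and in mt-Nd3 (5.62-fold), mt-Atp8 (3.78-fold), Wdr89 (4.86-fold), Rps27rt (4.64-fold), Rps21 (3.48-fold) and Rps28 (3.39-fold). The last 6 genes also led the genes higher in design 1 in conventional DC-like cells, where mt-Nd3 stood at 18.8-fold and Rps21 at 7.09-fold. Immediate early genes were lower in design 1 in T-like cells (median log2 −1.15, 10 of 12 lower) and in neutrophil-like cells (−2.57, 11 of 11).

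**Figure D4:**
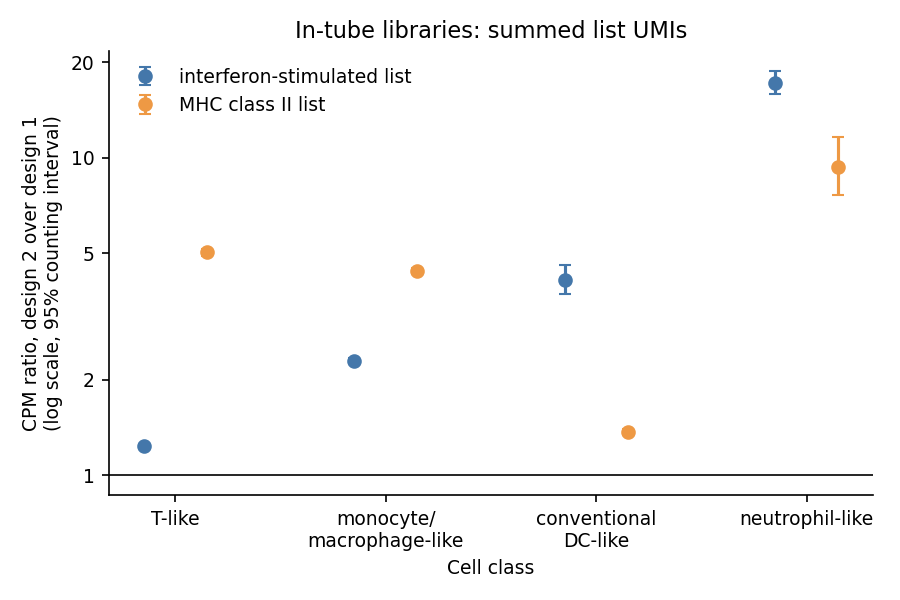
Ratio of CPM in design 2 over design 1 (vertical axis, log scale) of the summed UMIs of the interferon-stimulated and MHC class II lists in 4 cell classes (horizontal axis), with 95% counting intervals. The interferon-stimulated list runs from 1.24-fold in T-like to 17.3-fold in neutrophil-like cells, the latter 1.95-fold with stricter cells.

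All 13 clusters of the wound healing library were fibroblast-like, and the cells carried matrix and contractile genes at high levels. All 9 matrix genes lay above the T-like cells of both lymph node libraries, which served as background. Col1a1, Col1a2, Col3a1, Postn and Sparc were also markers that named the clusters. Counts above this background set fibroblasts apart from T cells and say nothing about wound healing. Bgn stood at 1883 CPM (1874 to 1893), the collagen genes Col1a2 at 1541 and Col1a1 at 1219 (1212 to 1226), Sparc at 955 and fibronectin (Fn1) at 878. With every cell thinned to 2000 UMIs, a Col1a1 UMI was found in 85.4% (84.6% to 86.3%) of fibroblasts. Of 8 contractile genes 7 lay above the background, with Cald1 at 739.6 CPM, Tpm1 at 435, smooth muscle actin (Acta2) at 426 and Tagln at 251. An Acta2 UMI was found in 33.8% of thinned fibroblasts. Cnn1 stood at 0.827 CPM. Of 7 YAP targets 6 lay above, with Axl at 119.7, Cyr61 at 59.9 and Ctgf at 38.2 CPM. Of 9 matrix remodelling genes 5 did, with the protease inhibitor Timp1 at 169.8 and the proteases Mmp14 at 145 and Mmp2 at 137 CPM. Mmp3, Mmp10 and Mmp13 had no UMI, which allows up to 0.0436 CPM.

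Division and stress genes of the fibroblasts were mixed. Of 12 G2/M genes 8 lay above the background, with Ube2c at 42.7, Birc5 at 42.4 and Top2a at 37.9 CPM, and of 13 S phase genes 2 did. So did 6 of 10 hypoxia, 5 of 11 glycolysis, 3 of 8 heat shock, 7 of 10 mitochondrially encoded and 2 of 12 immediate early genes (Egr1 at 118 and Ier3 at 89.1 CPM). None of 14 interferon-stimulated or 10 ribosomal protein genes and 1 of 7 MHC class II genes did. The library's 6848 cells had a median of 11365.5 UMIs against 2200 and 3273 in the background cells, of which 3766 and 3906 reached 2000 UMIs. The background share was 0% and 0.0512% for Col1a1 and 0% in both for Acta2. The library had no replicate, and its intervals cover counting error only.

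On the mouse assembly GRCm38, the annotation places the genes that stand for these comparisons as protein-coding genes. Gzmk (ENSMUSG00000042385) lies on chromosome 13 from 113171608 to 113225908, Ccr7 (ENSMUSG00000037944) on chromosome 11 from 99144196 to 99155077, and Klf2 (ENSMUSG00000055148) on chromosome 8 from 72319033 to 72321656. Nr4a1 (ENSMUSG00000023034) lies on chromosome 15 from 101254269 to 101274795, Pdcd1lg2 (ENSMUSG00000016498) on chromosome 19 from 29410919 to 29471161, Saa3 (ENSMUSG00000040026) on chromosome 7 from 46711998 to 46715700, and Col1a1 (ENSMUSG00000001506) on chromosome 11 from 94936224 to 94953042. Lars2 (ENSMUSG00000035202) lies on chromosome 9 from 123366927 to 123462666, and stood at 68.6 to 159.6 CPM in 11 classes of the tumour libraries and at 0 to 11.7 CPM in 20 classes of the other 5 libraries.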

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

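The tests in this part were chosen after the result was seen, except the tests of mCherry UMIs and of unrelated cell pairs, which were written down before. The log2 change in NK-like minus that in T-like cells was −7.00 for Ccl3, −5.68 for Ccl5, −1.94 for Nkg7 and −2.24 for Cd160. It was −2.28 for Zfp36, −2.76 for Fosb, −3.91 for Birc5, −2.64 for Tyms, −3.61 for Ifit1, −2.96 for Ifit3 and 2.76 for Satb1. Without lymph node library 2 the difference was 9.23 for Ifit1 and 0.81 for Ifit3.

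A pa-gfp UMI was found in 15.6% (13.3% to 18.2%) and 24.8% (22.6% to 27.1%) of T-like cells of tumour libraries 1 and 2. NK-like cells served as background, at 0% (0 of 186, interval up to 1.96%) and 3.08% (1.42% to 5.77%). The median depths were 9246.5 and 9556.5 UMIs in T-like and 7719.5 and 7620.5 UMIs in NK-like cells. Thinned to 5000 UMIs, the shares were 15.5% and 24.9% against 0% and 1.55%, and against 4.82% in conventional DC-like and 4.19% in monocyte/macrophage-like cells of tumour library 2 (medians of 23138 and 28584 UMIs, unthinned shares 7.51% and 9.24%). An egfp UMI was found in 13.2% and 21.3% of T-like cells against 0% and 1.03% of NK-like cells. A dsredexpress1 UMI was found in 3.66% (3.11% to 4.29%) of T-like cells of lymph node library 2 (median 3273 UMIs) against 0.347% of its B-like cells (median 2225.5 UMIs). Thinned to 2000 UMIs the shares were 2.20% (1.76% to 2.71%) and 0.515% (0.0130% to 2.84%), with overlapping intervals. In a T-like cluster of 1083 cells, picked after its share was seen, the share was 10.5%. Thinned, it was 6.15% (4.79% to 7.76%), above the B-like interval. In the largest T-like cluster (1511 cells) the thinned share was 0.282%. The reporter features took part in the clustering, so cluster shares may partly restate it.

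A cluster led by the melanin synthesis genes Dct, Pmel, Tyrp1 and Mlana held 152 cells, 2.46% (2.09% to 2.88%), of tumour library 1 and 42 cells, 1.05% (0.759% to 1.42%), of tumour library 2, although the labels describe CD45+ immune cells. A UMI of Ptprc, which encodes CD45, was found in 27.0% and 21.4% of these cells (median 61989 and 102516 UMIs) against 99.5% and 99.4% of T-like cells (9246.5 and 9556.5 UMIs). Mammary epithelial cells are argued against by a median of at most 0.658% of the cells with an epithelial marker, and free RNA by levels of the 6 melanocyte genes that were a median of 16.7 times (lowest 6.39) those in barcodes under 100 UMIs in tumour library 1, the lower of the libraries. The tumour line's mCherry reporter cannot be told apart from another origin, because 0 mCherry UMIs were found in any barcode of either library, so its absence from the cluster, which the written prediction would have counted against it, carries no weight. No biological explanation other than mammary epithelial cells was tested, and the origin of these cells stays open.

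The tumour libraries shared 625 cell barcodes, where chance would give 3.63 and at most 8, so chance reuse is argued against. The smaller copy held a near-constant share of the UMIs of the larger, 2.49% where the larger lay in tumour library 2 and 1.18% where it lay in tumour library 1, with a quartile ratio of at most 1.08. Its genes were those of its partner more often than those of another cell, by a median of 6.10 percentage points in tumour library 1 and 5.12 in tumour library 2, which argues against unrelated pairs. Molecules of a library counted in the other during sequencing are a candidate explanation that these values leave standing. Cells with a larger copy of their barcode in the other library, counted there whether or not it passed the cell filters, were 579 (9.36%) in tumour library 1, 537 of them unnamed, and 99 (2.48%) in tumour library 2, 89 of them unnamed.

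Lars2 was higher and Rps27rt lower in the tumours in every class tested. The lowest Lars2 level of 11 tumour classes was 5.87 times the highest of 20 classes of the other libraries, but Rps27rt levels overlapped, up to 101 CPM in the tumours and down to 93.0 CPM elsewhere. A difference confined to T cells is argued against, because Lars2 in monocyte/macrophage-like cells was at least 7.22 times as high in the tumour as in the in-tube libraries. A difference of library kit or run and a difference of tissue cannot be told apart, because kit and tissue were split the same way and Rps27rt did not separate the libraries. Ranges overlapped as well for Rnaset2b (5.28 to 31.9 CPM in the tumours, 12.4 to 421 elsewhere), Rps28 (259 to 1188, 594 to 6013) and Snrnp200 (31.6 to 69.9, 0 to 41.6). The shared split of kit and tissue bears on every change between tumour and lymph node. No biological explanation was tested.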

How the results depend on the processing

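Settings were changed singly. In T-like cells 915 of 921 gene values under other settings kept their result, 5 were weaker and 1 reversed, Apoe, at −9.73 after free RNA was subtracted. With a library left out 284 of 288 were the same and 4 weaker. The count of 5992 ran from 3431 to 5772 with a library left out, where the lone library of a tissue was assumed to vary like the other tissue. In NK-like cells 453 of 467 were the same and 14 weaker, and with a library left out 149 of 160 the same, 9 weaker and 2 reversed. These were Ifit1 (−3.81 to 7.32) and Ifit3 (−2.80 to 1.46). The count of 786 was 452 with DESeq2 and 420 with thinned counts. Without the low-count filter 62.8% of the called genes were higher, and with DESeq2 34.3%, against 49.1% in the main test. The causes were not tested.

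The count of 51 genes in conventional DC-like cells changed with most choices. It stayed at 50 with median-ratio size factors and 51 without shared barcodes. It was 332 with DESeq2, 1064 without the low-count filter, 2095 with looser and 2130 with stricter cells. It was 14 at the 20% mitochondrial limit, 96 with doublets kept, 100 at Leiden resolution 0.5 and 2073 with every cluster in its best class. It was 113 with thinned counts, 10 with the genes abundant in free RNA left out, and 0 with free RNA subtracted by edgeR (842 unadjusted). With a library left out it ran from 0 to 2386. Of 317 gene values 246 were the same, 26 stronger and 45 weaker, and of 100 with a library left out 51 were the same, 10 stronger and 39 weaker.

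Of the 13, 7 and 5 lists called in T-like, NK-like and conventional DC-like cells, 0 were called with an estimated correlation. That version had little power with so few libraries and cannot decide whether the calls hold. With a library left out 4 to 9 lists were called in NK-like and 5 to 10 in conventional DC-like cells. The 636 genes whose change differed between NK-like and T-like cells became 352 to 536 with a library left out and 651 with best classes, and the differences ran from −4.74 to 9.23 for Ifit1 and from −4.02 to 0.81 for Ifit3.

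The mean T-like share of the lymph nodes was 86.9% with best classes, 78.3% with doublets kept, 77.6% with looser and 77.9% with stricter cells, 79.1% at the 20% limit and 78.4% at resolution 0.5. In design 1 it was 91.8% with best classes, 64.6% looser, 82.8% stricter, 89.0% at the 20% limit and 89.8% at resolution 0.5, and monocyte/macrophage-like cells were 4.65% looser and 3.60% stricter. In design 2 T-like cells were 47.9% with best classes, 21.4% looser and 35.8% stricter. Monocyte/macrophage-like cells were 32.3% stricter, 25.3% with doublets and 29.8% at resolution 0.5.

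The interferon-stimulated list in T-like cells was 1.11-fold higher in design 2 with looser and 1.14-fold with stricter cells, 1.21-fold with doublets and 1.06-fold with median-ratio scaling. MHC class II was 4.56-fold stricter, 4.74-fold at the 20% limit, 5.36-fold with doublets and 4.32-fold with median-ratio scaling. In monocyte/macrophage-like cells the interferon-stimulated list was 2.37-fold looser, 2.37-fold with doublets and 2.44-fold with median-ratio scaling, and MHC class II 5.13-fold with doublets and 4.67-fold with median-ratio scaling. In neutrophil-like cells the interferon-stimulated list was 1.95-fold stricter, 11.1-fold looser and 12.3-fold with doublets, and MHC class II 5.13-fold looser. With stricter cells the cluster led by Lcn2 and Slpi left the class. In conventional DC-like cells MHC class II was 2.31-fold with doublets. Thinned to 2000 UMIs, the fibroblast shares were 85.4% for Col1a1 and 33.8% for Acta2, from 99.8% and 71.2%.

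Stricter cells were not possible in NK-like cells, of which fewer than 50 remained in a library. B-like cells did not reach 50 cells in every library, so the rule set for the tests left them untested. No test was possible in monocyte/macrophage-like cells, because no lymph node cluster took that name, or between region barcodes. No paired analysis was possible because the labels pair no tumour library with a lymph node library.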

Other observations

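The comparison of T-like cells with and without GFP was chosen after the reporter UMIs were seen. T-like cells of the tumours that carried GFP RNA were rich in CD8 and division genes. At least 2 pa-gfp or egfp UMIs were found in 118 and 327 T-like cells of tumour libraries 1 and 2, or 13.5% and 22.6%, and none in 740 and 1083. Cells with 1 UMI (18 and 38) and T-like cells that were smaller copies of a barcode shared by both tumour libraries were left out. GFP cells were deeper, with medians of 30329 and 16144 UMIs against 8566.5 and 8655. CD8 coreceptor genes were higher in GFP cells, Cd8a 3.73-fold and 3.27-fold and Cd8b1 2.08-fold and 2.42-fold. Dapl1 was higher by 7.23-fold and 3.53-fold, Prf1 by 2.27-fold and 1.51-fold, and Gzmb by 1.5-fold and 3.44-fold. The division genes Mki67 (1.61-fold and 1.46-fold) and Top2a (2.25-fold and 1.61-fold) were higher too. All 13 S phase and all 12 G2/M genes were higher in both libraries with intervals clear of no difference, but these cover counting error only. The dividing T-like clusters were the deepest (medians 35847.5 and 27139 UMIs), so asking for 2 reporter UMIs without thinning favoured dividing cells. Thinned to 5000 UMIs, pa-gfp was found in 48.6% and 50% of these clusters, against 15.5% and 24.9% of all T-like cells.

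Genes of helper, regulatory and resting T cells were lower in GFP cells. Cd4 was 31.3-fold and 12.2-fold lower, Foxp3 45.3-fold and 8.02-fold, Ikzf2 4.55-fold and 4.51-fold, the egress receptor S1pr1 14.3-fold and 4.85-fold, Klf2 6.56-fold and 6.96-fold, and Il7r 5.43-fold and 4.72-fold. Of 7 regulatory T cell genes 6 were lower in both libraries, of 10 naive and recirculating genes 8 were lower and 2 higher, and of 10 cytotoxic genes 5 were higher and 1 lower. Exhaustion and checkpoint genes were split, with 2 higher and 2 lower of 10. A pa-gfp UMI was found in 33.7% of the CD8-led cluster and 51.8% of the dividing T-like cluster of tumour library 1, and in 94.8% and 90.3% of the clusters of tumour library 2 led by pa-gfp and Gzmb and by Dapl1. In the dividing T-like cluster of tumour library 2 it was found in 52.5%. In each of these 5 clusters pa-gfp was itself among the 10 leading genes, so their shares partly restate the clustering. In monocyte/macrophage-like cells (median 20936 and 28584 UMIs) it was found in 2.02% and 9.24%, and in 0.337% and 4.19% after thinning to 5000 UMIs.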
